A study of Mus musculus with 24 samples.

How the data were processed

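Total RNA from whole mouse colon was measured on Affymetrix MOE430 arrays: 12 numbered samples, each on a 430A and a 430B array, in 4 groups of 3. The groups are the standard or the curcumin diet, each with control or TNBS enema. The deposited values are signals on a linear intensity scale that the authors made with GCOS, per the submitters' processing notes, and the GCOS version is not given in the sources used here. In the deposited signal tables the 2% trimmed mean of every array is near 500 (500.1 to 500.2 on 430A), so the arrays had been scaled to a common mean, and they were used as deposited. The arrays carry no read depth, and their number limits the precision. Detection calls were not used here. The median signal of the arrays ran from 226.7 to 284 on 430A and from 256.5 to 346.2 on 430B. As a check on the RNA, the ratio of 3' to 5' control probe sets for Gapdh was 0.700 to 0.874 on 430A and 0.721 to 0.935 on 430B, and for actin 1.04 to 1.24 and 1.02 to 1.19. For the transferrin receptor it was higher, 1.78 to 4.29 and 2.09 to 4.68. Of the 66 pairs of arrays of each type, 0 were identical.

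Probe sets were named with the platform annotation. On 430A, 20380 of 22626 probe sets have 1 gene symbol, 691 have several and 1555 have none. On 430B, 14661 of 22511 have 1, 245 have several and 7605 have none. The 64 control probe sets of each array type are left out of these numbers. No genome build is given, so no coordinates are printed.

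Signals were raised by a pseudocount of 16 and log2-transformed. Probe sets were kept when their mean log2 value over the 12 arrays of a type was above the 40th percentile, which left 13575 on 430A and 13506 on 430B. Each array type was fitted alone, with a mean per group over all 12 arrays, in limma 3.58.1 with R 4.3.3, using lmFit and eBayes with an intensity trend. The residual degrees of freedom were 8. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within an array type, and an adjusted p under 0.05 is called past the threshold. The contrasts were TNBS against control enema on each diet, curcumin against standard diet with each enema, their interaction, and the averages of enema over diets and of diet over enemas. Counts are sums over both array types.

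Gene level means 1 probe set per gene, the tested one with the highest mean, from 430A where the gene is tested there and otherwise from 430B. The 28 gene lists hold 656 genes, 591 of which are on the arrays and 457 of which were tested. The number of measured members and of those that rose or fell covers both array types. Lists were tested against the other genes with camera from limma on the 8348 genes of 430A, with a preset correlation of 0.01 and, as an alternative, with an estimated correlation. Camera p-values were adjusted over the 27 lists that could be tested in a contrast. Adjusted over the list alone means that the limma p-values of a list's members were adjusted among themselves.

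The rule for naming genes was fixed in advance, but not the choice of fits to which it was applied. It was applied to the planned fit and to a later fit, described below, that was chosen after the data were examined. For TNBS on the standard diet, genes such as Ngp, Tyrobp and Sparc did not pass in the planned fit. They entered only through the later one. For each single-factor contrast and the interaction, the rule takes genes past the threshold. Their arrays must not overlap between the groups compared, a condition dropped for the interaction. Named are the 8 with the largest rise, the 8 with the largest fall and up to 3 members of each list with the largest absolute change, as far as there is room. Where fewer than 5 genes passed, the rule takes those and the 5 with the smallest p as values, also as far as there is room. Left out of the text are, for instance, Cd52, Foxo4, Lurap1 and Trub1 for TNBS on curcumin and Csf2rb for TNBS on the standard diet. Il1b, Tnf, Il6, Ifng, Il10, Il11, Foxp3, Il17a, Nos2, Ptgs2, Hmox1, Nqo1, Cyp1a1, Gstm1 and Muc2 are named whatever their p. Other genes, such as Cpa1, Prss2, Insig1 and those given only to show a probe set or a fit that differs, were chosen after their values were seen.

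The contrasts, the lists, the filter, the tests and a set of other settings were chosen before the data were examined. These settings were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, centring on the median, eBayes without a trend, array weights, only the 6 arrays of the groups compared, each sample left out in turn, an adjusted p under 0.01, and a change of at least 1.5-fold. For the lists they were an estimated correlation, the mean of a gene's probe sets, quantile normalization and each sample left out in turn. Added after the data were examined were a term for the 2 sets of 430A arrays that the first principal component parts, a fit of 430B without the 2 arrays whose first principal component lies more than 5 median absolute deviations from the median, which leaves 1 array of the curcumin-diet TNBS group, assumed to vary like those of the other groups, both of these together, and the array set together with a pancreas score, the mean log2 value of the pancreas list on each 430A array. The pancreas list for 430B was also written after the data were examined.

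The agreement of the TNBS effects is a Pearson correlation over the 8348 genes. For comparisons that share arrays, 200 seeded simulations with no effect and independent noise per gene gave the value that the shared arrays alone produce. They gave it for the overlap of calls as well. Group labels were also exchanged within each contrast. All splits of the samples were used for the single-factor contrasts. For the interaction and the 2 averages 100 splits were used, the real one and a random draw of the others.

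The scripts were tested on simulated data made from the real arrays of TNBS against control enema on the standard diet, with 13575 probe sets, 200 of them changed, in 5 runs. With simulated array sets, the planned fit recovered 5.60%, 56.8%, 97.2% and 98.4% of changes of 0.5, 1, 2 and 3 log2, and the fit with the array set 18.8%, 83.2%, 100% and 100%. Of 66875 unchanged probe sets, 6 and 38 were called. The list test called 15 of 15 lists shifted by 0.5 log2 and 1 of 120 others, on 8348 genes. Its simulated arrays had independent genes and no array sets. It therefore does not show how often lists of correlated genes are called without a shift.

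To see whether equal numbers mark equal samples on both array types, the residuals of 100 probe sets present on both were correlated. The mean was 0.175 for equal numbers and -0.0158 for unequal ones, and 7 of 12 samples fitted best with their own number.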

Results

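Colon RNA from BALB/c mice, an inbred laboratory strain, was profiled on 24 Affymetrix MOE430 arrays, 12 of the 430A and 12 of the 430B type. The mice were 6 to 8 weeks old and ate a standard diet or a diet with 2% curcumin, the yellow polyphenol of turmeric. The diets began 2 days before an enema of either control solution or trinitrobenzene sulfonic acid (TNBS), a hapten that causes colitis when it is given into the colon. The whole colon was taken on day 7 after the enema on day 0. Diet and enema cross into 4 groups with 3 numbered samples each, and the labels give each number to 1 array of each type. The study asks how dietary curcumin changes colonic gene expression in this colitis. Per the labels, RNA was pooled from 3 mice of a group, and they do not say whether the 3 samples of a group are separate pools. The errors given here are therefore spreads between these samples, which may not equal spreads between mice. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.198 on 430A and 0.257 on 430B.

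The strongest division among the 430A arrays did not follow diet or enema. The first principal component carried 32.0% of the variance and parted the arrays into 2 sets of 6, called array set 1 and array set 2 here. Each group has 1 or 2 arrays in each set. The mean correlation was 0.943 within a set and 0.912 between sets, against 0.927 within a group and 0.926 between groups. On 430B, the arrays of curcumin-diet TNBS replicates 2 and 3 stood apart: their mean correlation with the other 10 arrays was 0.770, against 0.904 among those 10. The labels name no batch. Both features were found in the values, so the fits that take them into account were chosen after the data were examined. Counts from the planned fit are given as such. Log2 differences are given ± their standard error. Medians and camera p-values of lists, and their runs with 1 sample left out, come from the planned fit unless the array set is named. Log2 differences of single genes come from later fits unless the planned fit is named. The numbers of list members that rose or fell over all genes come from them too. These later fits have the array set as a term on 430A and leave out the 2 outlying arrays on 430B. Each group has 3 arrays in these fits, except that the curcumin-diet TNBS group is left with 1 array on 430B, which is assumed to vary like the arrays of the other groups. Values within array set 1 and within array set 2 rest on 1 or 2 arrays per group.

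**Figure D1:**
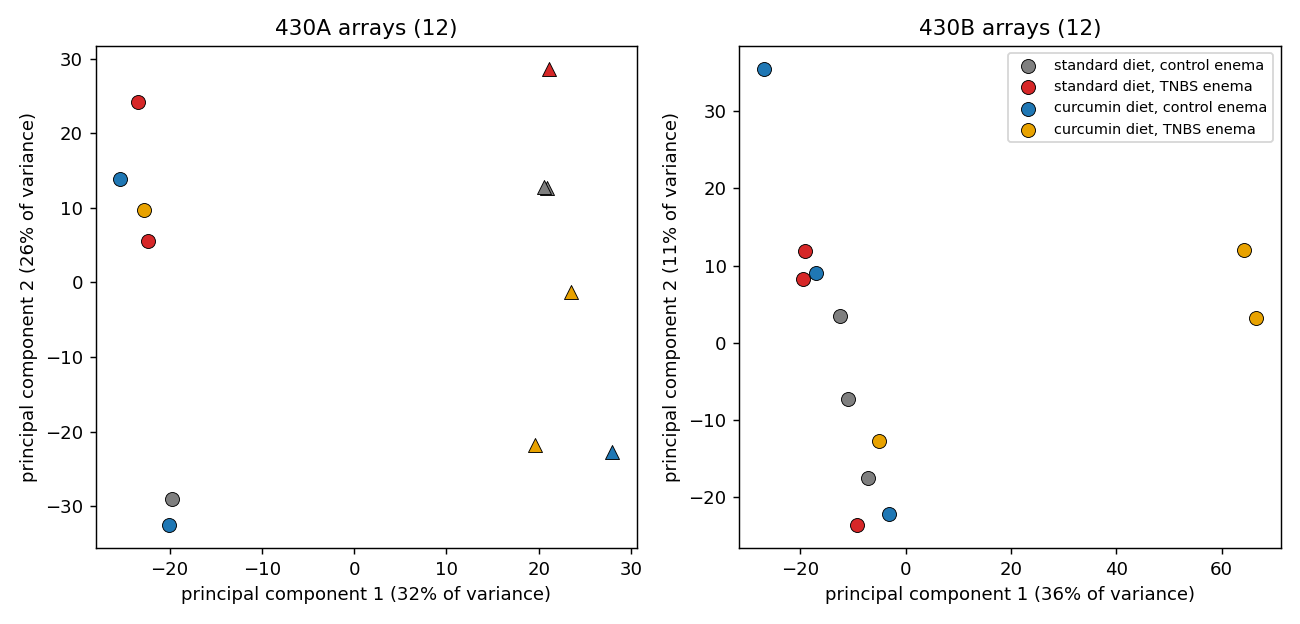
Each point is an array placed by its first (x) and second (y) principal component of log2 signal (no unit), with colour for the 4 groups and, on 430A, circles for array set 1 and triangles for array set 2. On 430A the first component, 32% of the variance, parts the 2 sets of 6 arrays, and on 430B 2 of the 3 curcumin-diet TNBS arrays lie far from the other 10.

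The comparison of TNBS with control enema on the standard diet asks what the colitis changed in the colon 7 days on. Lcn2, which encodes the iron-scavenging protein lipocalin 2, rose most: its signal was 81.4 ± 29.7 in the control group and 4892 ± 1681 in the TNBS group (SD, n = 3). Its log2 difference was 5.63 ± 0.59, adjusted p = 0.00638 in the planned fit, 5.60 ± 0.61, adjusted p = 0.00988 with the array set as a term, and 5.82 and 5.81 within the 2 sets. Clca4b, of the family of calcium-activated chloride channel accessory proteins and measured on 430B, rose by 5.06 ± 0.53, adjusted p = 0.00178 in the planned fit, from 270.4 ± 47.4 to 10820.5 ± 5886 (SD, n = 3). Saa3, a serum amyloid of the acute phase, rose by 3.32 ± 0.46, adjusted p = 0.0320 (3.37 and 3.42 within the sets). The antimicrobial lectins Reg3g (3.20 ± 0.52, adjusted p = 0.0391) and Reg3b (1.90 ± 0.35, adjusted p = 0.0485) and the antibacterial phospholipase Pla2g2a (2.82 ± 0.53, adjusted p = 0.0485) rose as well. The within-set values of Reg3g were 2.99 and 4.05, and another Reg3b probe set had 0.97 (adjusted p = 0.169). In the planned fit, Saa3 and Reg3g had adjusted p = 0.0593 and 0.0593, so only Lcn2 and Clca4b passed there.

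Some cytokine and leukocyte genes rose as well. Il1b, the gene of interleukin 1 beta, rose by 1.69 ± 0.26, adjusted p = 0.0376 with the array set as a term, and by 1.79 and 1.40 within the sets. Vcam1 of activated endothelium (1.02 ± 0.19) and the lipopolysaccharide-binding protein gene Lbp (1.24 ± 0.20) also passed. The neutrophil granule genes Mmp8 (1.42 ± 0.21), Ngp (1.26 ± 0.17) and Mmp9 (1.17 ± 0.21) and the myeloid signalling adaptor Tyrobp (0.81 ± 0.14) rose. The genes named here did not pass in the planned limma fit. Their adjusted p there was 0.0593 for Il1b and Lbp, 0.0974 for Mmp8, Mmp9 and Tyrobp and 0.265 for Ngp. Of the 19 measured inflammatory cytokines, chemokines and mediators, 4 rose and 0 fell (8 and 0 adjusted over the list alone) and 15 did not pass. The list stood higher (median log2 difference 0.37, 0.33 with the array set in the model, 0.26 and 0.26 within the sets; adjusted p = 1.04e-09, or adjusted p = 0.0302 with an estimated correlation). Of 12 neutrophil markers, 4 rose and 0 fell (11 and 0 over the list alone), and the list stood higher (median log2 difference 0.86, 0.99 with the array set in the model, 0.83 and 1.06 within the sets; adjusted p = 1.59e-10, or adjusted p = 0.0731 with an estimated correlation). Of 19 monocyte and macrophage markers, 1 rose and 0 fell (11 and 0 over the list alone), and the list stood higher (median log2 difference 0.34, 0.39 with the array set in the model, 0.36 and 0.50 within the sets; adjusted p = 3.22e-08, or adjusted p = 0.0477 with an estimated correlation). With the array set as a term the estimated-correlation values were adjusted p = 0.0907, 0.0907 and 0.0426 for these 3 lists, so only the macrophage list stayed called. The T and NK cell list of 7 measured genes had a median of 0.19 (adjusted p = 0.0475, or adjusted p = 0.394 with an estimated correlation). With 1 sample left out its median ran from 0.03 to 0.29, and it was called in 7 of 12 runs. The cell cycle list, with 0 of 26 members past the threshold, had a median of 0.25, but 0.04 and 0.50 within the sets (adjusted p = 7.42e-05, or adjusted p = 0.344 with an estimated correlation). It ran from 0.05 to 0.39 with 1 sample left out and was called in 11 of 12 runs.

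Of the 26 measured genes of the extracellular matrix and its remodelling, 3 rose. The protease inhibitor gene Timp1 rose by 2.47 ± 0.39, adjusted p = 0.0376, the fibril-associated collagen gene Col12a1 by 2.23 ± 0.43, adjusted p = 0.0485 and the matricellular protein gene Sparc by 0.80 ± 0.15, adjusted p = 0.0485. Other probe sets had 0.87 for Col12a1 (adjusted p = 0.723) and 0.93 and 0.16 for Sparc. The 3 genes did not pass in the planned limma fit (adjusted p = 0.0593 for Timp1, 0.159 for Sparc and 0.180 for Col12a1). Of the list, 3 rose and 0 fell, and 19 and 1 did adjusted over the list alone. The list stood higher (median log2 difference 0.65, 0.65 with the array set in the model, 0.66 and 0.68 within the sets; adjusted p = 8.19e-19, or adjusted p = 0.0774 with an estimated correlation). The endoplasmic reticulum stress list of 20 genes also stood higher, with 0 members past the threshold (median log2 difference 0.24, 0.21 with the array set in the model, 0.08 and 0.35 within the sets; adjusted p = 3.28e-06, or adjusted p = 0.168 with an estimated correlation). Smooth muscle markers had a median of -0.08 (adjusted p = 0.128) and of -0.19 with the array set as a term (adjusted p = 0.000737, or adjusted p = 0.146 with an estimated correlation). Pancreas acinar markers had a median of 1.93 (adjusted p = 0.103).

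Among the genes that fell were 4 of detoxification and 2 of the absorptive epithelium. The glucuronosyltransferase gene Ugt2b5 fell by 1.30 ± 0.25 (adjusted p = 0.0485, -1.26 and -1.30 within the sets). The log2 difference was -0.95 ± 0.16, adjusted p = 0.0457 for Cyp4f14, a P450 of fatty acid hydroxylation, -0.89 ± 0.13, adjusted p = 0.0320 for the drug efflux pump Abcb1a and -0.52 ± 0.10, adjusted p = 0.0485 for the retinal dehydrogenase Aldh1a1. Of 34 measured genes of P450 and other xenobiotic metabolism, 0 rose and 4 fell (0 and 16 over the list alone). The list stood lower (median log2 difference -0.50, -0.47 with the array set in the model, -0.51 and -0.58 within the sets; adjusted p = 1.61e-13, or adjusted p = 0.0731 with an estimated correlation). Among 30 absorptive colonocyte markers, 0 rose and 2 fell (1 and 6 over the list alone), namely the sulfotransferase Sult1a1 (-1.20 ± 0.20) and the phosphate transporter Slc20a1 (-0.90 ± 0.16, with -0.74 and -0.39 for its other probe sets); the list median was -0.20 (adjusted p = 0.000575, or adjusted p = 0.344 with an estimated correlation). Optc (-1.29 ± 0.24), Rgs17 (-1.20 ± 0.19) and Ngef (-1.02 ± 0.19) were the other largest falls, though a Rgs17 probe set on 430B had -0.05. The genes named here as lower did not pass in the planned limma fit. Their adjusted p there was 0.0747 for Abcb1a and 0.0974 for Ugt2b5, Aldh1a1 and Slc20a1. For Sult1a1 it was 0.132, for Ngef 0.134, for Optc 0.137, for Rgs17 0.278 and for Cyp4f14 0.373. Fatty acid metabolism and PPAR targets had a median of -0.19 (adjusted p = 0.00788, or adjusted p = 0.476 with an estimated correlation) and were called in 9 of 12 runs with 1 sample left out. Enteroendocrine markers had a median of -0.23 (adjusted p = 0.0117, or adjusted p = 0.1005 with an estimated correlation). They and the absorptive markers were called in 11 of 12 such runs. Adipocyte markers moved the same way: the 9 genes had a median of -0.52 and -0.41 and -1.08 within the sets (adjusted p = 9.75e-05, or adjusted p = 0.276 with an estimated correlation).

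The goblet and secretory list moved in both directions. Of 22 measured members, 3 rose and 1 fell (7 and 2 over the list alone). Reg3g, Pla2g2a and Reg3b rose, while Atoh1, the transcription factor of the secretory lineage, fell by 0.54 ± 0.09 (adjusted p = 0.0457). The mucin gene Muc2 had a log2 difference of 0.09 ± 0.21 (adjusted p = 0.984). The list median was 0.25 (adjusted p = 4.18e-05, or adjusted p = 0.168 with an estimated correlation).

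In the planned fit, 2 probe sets were higher and 0 were lower in this comparison out of 27081 tested, with 1968 at unadjusted p under 0.05 in limma. After quantile normalization the split was 10 higher and 4 lower. With the array set as a term on 430A and without the 2 outlying 430B arrays, 35 were higher and 29 were lower, all but 1 of them on 430A. Leaving out a sample and keeping the array set as a term moved the 430A count of 63 between 0 (without standard-diet control replicate 1 or 3, or standard-diet TNBS replicate 1 or 3) and 292 (without curcumin-diet control replicate 3). Clca4b passed in 12 of 12 leave-one-out runs of the planned fit and Lcn2 in 8 of 12.

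**Figure D2:**
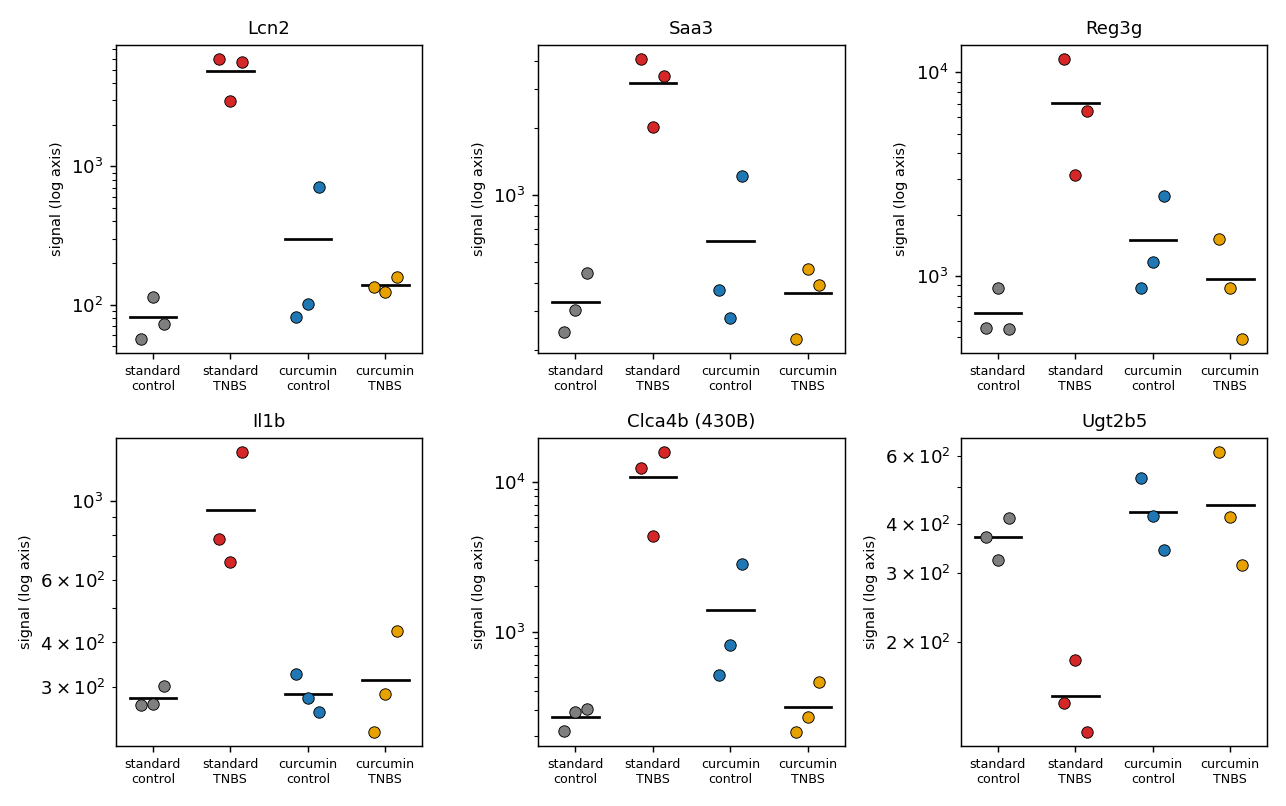
Each point is the signal (intensity, log axis) of Lcn2, Saa3, Reg3g, Il1b, Clca4b or Ugt2b5 on an array, the x axis gives the 4 groups and each bar marks the mean of 3 arrays. The 3 standard-diet TNBS arrays had Lcn2 signals of 6003, 2957 and 5714, above all other arrays, and curcumin-diet control replicate 3 had 710.1, the highest of the rest.

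The comparison of the curcumin with the standard diet under the control enema asks what curcumin changed in a colon without TNBS. In the planned fit 1 probe set passed, of Ttc3, a ubiquitin ligase gene, on 430B (-2.32 ± 0.30, adjusted p = 0.0204). The 5 other probe sets of Ttc3 had log2 differences of -0.25 to 0.35, so this call describes a single probe set rather than the gene. In the fit with the array set as a term and without the outlying 430B arrays, the genes with the smallest p did not pass. They were the intestinal lectin gene Itln1 (-2.62 ± 0.38, adjusted p = 0.0956), the aldo-keto reductase gene Akr1b8 (0.82 ± 0.13, adjusted p = 0.0956), Atoh1 (-0.56 ± 0.09, adjusted p = 0.134), the Paneth-cell ribonuclease gene Ang4 (-1.97 ± 0.34, adjusted p = 0.280) and the stress transcription factor gene Ddit3 (1.45 ± 0.27, adjusted p = 0.297). The other Ddit3 probe set, on 430B, had -0.24. In the planned fit these genes lay further from the threshold. The adjusted p in limma was 0.998 for Itln1 and Atoh1, 0.835 for Ddit3, 0.665 for Ang4 and 0.279 for Akr1b8. The mean Itln1 signal was 546 ± 405 on the standard and 90.3 ± 59.2 on the curcumin diet, and that of Akr1b8 was 1445 ± 255 and 2673 ± 222 (SD, n = 3). Within the array sets Itln1 differed by -3.08 and -2.37 and Akr1b8 by 0.76 and 0.87.

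At the level of lists, the 2 that stayed called with an estimated correlation were endoplasmic reticulum stress and cholesterol synthesis. The endoplasmic reticulum stress list stood higher (median log2 difference 0.33, 0.31 with the array set in the model, 0.25 and 0.33 within the sets; adjusted p = 1.21e-20, or adjusted p = 0.0223 with an estimated correlation). With the array set as a term, the estimated-correlation value was 0.0976. Of its 20 members 0 passed over all genes and 10 were higher adjusted over the list alone. The chaperone genes Hspa5 (0.85 ± 0.16) and Hsp90b1 (0.64 ± 0.12) had adjusted p = 0.556 and 0.556 in the planned fit. Other probe sets had 1.32 and -0.09 for Hspa5 and 0.18 for Hsp90b1. The cholesterol synthesis list stood higher (median log2 difference 0.26, 0.29 with the array set in the model, 0.20 and 0.37 within the sets; adjusted p = 2.15e-06, or adjusted p = 0.0178 with an estimated correlation), and with the array set as a term the estimated-correlation value was 0.0402. Of 17 measured members 0 passed over all genes, and 1, the sterol sensor Insig1 (0.67 ± 0.16), was higher over the list alone. Nrf2 targets and glutathione enzymes had a median of 0.19 (0.08 and 0.19 within the sets, adjusted p = 1.66e-06, or adjusted p = 0.285 with an estimated correlation). The cell cycle list had a median of 0.15 (adjusted p = 0.0334, or adjusted p = 0.813 with an estimated correlation), but from -0.08 to 0.30 with 1 sample left out, so that its sign is not settled. The lower lists were enteroendocrine markers (-0.17; adjusted p = 0.0124, or adjusted p = 0.136 with an estimated correlation) and MHC class II genes (-0.20; adjusted p = 0.0153, or adjusted p = 0.388 with an estimated correlation). The cell cycle and MHC class II lists were each called in 9 of 12 runs with 1 sample left out. Pancreas acinar markers had a median of -2.26, but 2.73 and -5.64 within the sets (adjusted p = 2.64e-05, or adjusted p = 0.645 with an estimated correlation). They and the enteroendocrine markers were called in 11 of 12 runs. Smooth muscle markers had a median of -0.15 with the array set as a term (adjusted p = 0.000924, or adjusted p = 0.181 with an estimated correlation).

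In this comparison 977 probe sets had unadjusted p under 0.05 in the planned limma fit, 415 of them on 430A, where 0 passed. With the array set as a term and without the outlying arrays the count past the threshold was 0, with 1460 at unadjusted p under 0.05.

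The comparison of TNBS with control enema on the curcumin diet asks what the enema changed under curcumin. The inflammation genes that rose on the standard diet did not pass here. Lcn2 had a log2 difference of -0.36 ± 0.61, adjusted p = 0.957, Saa3 of -0.64 ± 0.46, adjusted p = 0.917, Reg3g of -0.60 ± 0.52, adjusted p = 0.917 and Il1b of 0.03 ± 0.26, adjusted p = 0.991. The signal of Lcn2 was 298 ± 357 in the control and 139 ± 18.4 in the TNBS group (SD, n = 3). Curcumin-diet control replicate 3 had a higher signal than the other 2 control samples for Lcn2 (710.1, against 82.1 and 101), Saa3 (1209.6, against 372 and 278) and Clca4b (2830.0, against 510.1 and 808). The planned fit called 16 probe sets higher and 39 lower, all on 430B (6 and 32 after quantile normalization, 7 and 52 with arrays centred on their median). Among them were Teddm2 (1.94 ± 0.36) on the higher side and Stoml1 (-2.64 ± 0.51), Cdc42bpb (-2.39 ± 0.47) and Prdm11 (-2.34 ± 0.41) on the lower. Without the 2 outlying arrays, which leaves 1 array in the TNBS group, 0 of these 55 passed, 46 of them kept at least 0.5 of their size, and all kept their sign. The 55 calls were made with the remaining TNBS array among the 3, so the kept signs and sizes are in part built in. Without the outlying arrays Prdm11 was -2.37 ± 0.50, Teddm2 1.20 ± 0.47, Cdc42bpb -1.0025 ± 0.44 and Stoml1 -0.996 ± 0.34. The 2 probe sets that passed in that fit were both lower, the RNA helicase gene Dhx29 (-2.64 ± 0.37) and a probe set without a gene. The other probe set of Dhx29 had -0.13. On 430A 0 probe sets passed in limma, with 373 at unadjusted p under 0.05.

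Of the gene lists, 5 differed between TNBS and control enema on the curcumin diet, and 0 passed with an estimated correlation. The endoplasmic reticulum stress and cell cycle lists, which stood higher with TNBS on the standard diet, stood lower here. The median for endoplasmic reticulum stress was -0.21, and -0.16 with the array set (adjusted p = 1.14e-06, or adjusted p = 0.406 with an estimated correlation). Heat shock genes stood lower too (median -0.26 without and -0.18 with the array set; adjusted p = 1.53e-05; adjusted p = 0.434 with an estimated correlation). The cell cycle list had a median of -0.20 (adjusted p = 0.00805, or adjusted p = 0.859 with an estimated correlation) and was called in 9 of 12 runs with 1 sample left out. MHC class II genes stood higher (median 0.26 without and 0.22 with the array set; adjusted p = 1.40e-05; adjusted p = 0.310 with an estimated correlation). Pancreas acinar markers had a median of 1.36 (3.58 and 1.21 within the sets, adjusted p = 0.00937, or adjusted p = 0.859 with an estimated correlation). With 1 sample left out their median ran from 0.12 to 3.06, and they were called in 9 of 12 runs, while heat shock genes ran from -0.52 to -0.09 and were called in 11. The inflammatory list had a median of -0.16 (adjusted p = 0.0543) and the neutrophil list of -0.06 (adjusted p = 0.327).

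The comparison of the diets under TNBS asks what curcumin changed in the challenged colon. Lcn2 was lower on curcumin, with a log2 difference of -4.92 ± 0.59, adjusted p = 0.0139 in the planned fit, -4.89 ± 0.61, adjusted p = 0.0102 with the array set as a term and -4.78 and -5.27 within the sets. For Clca4b the difference was -4.91 ± 0.53, adjusted p = 0.00260 in the planned fit and -5.36 ± 0.76, adjusted p = 0.0435 without the 2 outlying arrays, where the curcumin-diet TNBS group has 1 array. Its signals on the 3 curcumin-diet TNBS arrays were 214, 268 and 459. Saa3 (-3.21 ± 0.46, adjusted p = 0.0222), Timp1 (-2.24 ± 0.39, adjusted p = 0.0446), the granulocyte growth factor receptor gene Csf3r (-1.82 ± 0.32, adjusted p = 0.0446), Lbp (-1.58 ± 0.20, adjusted p = 0.0102), Il1b (-1.57 ± 0.26, adjusted p = 0.0426), Ngp (-1.45 ± 0.17, adjusted p = 0.0102) and the cytokine gene Tgfb1 (-0.76 ± 0.14, adjusted p = 0.0460) were lower as well. The other Tgfb1 probe set, on 430B, had 0.44. Of these 7 genes from Saa3 to Tgfb1, only Lbp passed in the planned fit (adjusted p = 0.0139). The planned adjusted p was 0.0579 for Saa3, 0.0907 for Timp1 and Il1b, 0.104 for Tgfb1, 0.143 for Csf3r and 0.182 for Ngp. Xenobiotic and oxidative genes were higher on curcumin. They were Ugt2b5 (1.52 ± 0.25, adjusted p = 0.0426), Cyp4f14 (0.98 ± 0.16, adjusted p = 0.0426), Abcb1a (0.93 ± 0.13, adjusted p = 0.0132), Aldh1a1 (0.78 ± 0.10, adjusted p = 0.0102) and the catalase gene Cat (0.83 ± 0.11, adjusted p = 0.0118, with 0.36 and adjusted p = 0.432 for its other probe set). Slc20a1 (1.01 ± 0.16), Optc (1.42 ± 0.24) and the clock-interacting gene Cipc (0.99 ± 0.15) were higher too. Other probe sets had 0.35 and 0.46 for Slc20a1 and 0.97 and 0.55 for Cipc. Of the genes named here as higher on curcumin, only Aldh1a1 passed in the planned fit (adjusted p = 0.0172). The planned adjusted p was 0.0706 for Ugt2b5, Abcb1a and Slc20a1, 0.107 for Cat, 0.138 for Optc, 0.160 for Cipc and 0.330 for Cyp4f14. The mean Aldh1a1 signal was 2854 ± 288 on the standard and 4987 ± 126 on the curcumin diet, and that of Lcn2 was 4892 ± 1681 and 139 ± 18.4 (SD, n = 3).

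The inflammatory, neutrophil, macrophage and interferon lists were lower on curcumin under TNBS. Of 19 inflammatory genes 0 rose and 3 fell (0 and 11 over the list alone), and the list stood lower (median log2 difference -0.48, -0.41 with the array set in the model, -0.52 and -0.38 within the sets; adjusted p = 8.88e-11, or adjusted p = 0.0205 with an estimated correlation). With the array set as a term the estimated-correlation value was 0.0648. Of 12 neutrophil markers 0 rose and 2 fell (0 and 7 over the list alone), and the list stood lower (median log2 difference -0.95, -1.01 with the array set in the model, -1.05 and -0.93 within the sets; adjusted p = 3.21e-10, or adjusted p = 0.0651 with an estimated correlation). Monocyte and macrophage markers (median -0.32 without and -0.39 with the array set; adjusted p = 1.04e-05; adjusted p = 0.0651 with an estimated correlation) and interferon response genes (median -0.21 without and -0.20 with the array set; adjusted p = 0.00411; adjusted p = 0.109 with an estimated correlation) stood lower. Of 26 matrix genes 0 rose and 1 fell (1 and 16 over the list alone), and that list stood lower (median log2 difference -0.57, -0.52 with the array set in the model, -0.52 and -0.64 within the sets; adjusted p = 1.03e-12, or adjusted p = 0.128 with an estimated correlation). Lower as well were the goblet and secretory list (median -0.27; adjusted p = 1.04e-05, or adjusted p = 0.128 with an estimated correlation) and the cell cycle list (median -0.28; adjusted p = 3.71e-05, or adjusted p = 0.311 with an estimated correlation). Heat shock genes (median -0.22; adjusted p = 0.0191, or adjusted p = 0.356 with an estimated correlation) and immediate early genes (median -0.25; adjusted p = 0.0173, or adjusted p = 0.147 with an estimated correlation) did not keep their call with the array set as a term (adjusted p = 0.123 and 0.0550), and each was called in 10 of 12 runs with 1 sample left out. Pancreas acinar markers had a median of -2.79, but 0.63 and -4.72 within the sets (adjusted p = 0.00491, or adjusted p = 0.468 with an estimated correlation), and -4.27 to -0.87 with 1 sample left out.

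Xenobiotic, lipid and absorptive colonocyte lists were higher on curcumin under TNBS. Of 34 xenobiotic metabolism genes 4 rose and 0 fell (19 and 0 over the list alone), and the list stood higher (median log2 difference 0.56, 0.54 with the array set in the model, 0.45 and 0.63 within the sets; adjusted p = 4.08e-15, or adjusted p = 0.0595 with an estimated correlation). Absorptive colonocyte markers (median 0.13 without and 0.16 with the array set; adjusted p = 0.00114; adjusted p = 0.321 with an estimated correlation) and fatty acid metabolism and PPAR targets (median 0.22 without and 0.25 with the array set; adjusted p = 0.000428; adjusted p = 0.324 with an estimated correlation) stood higher. With 1 sample left out, the absorptive median ran from 0.000377 to 0.26, and the call was lost in 1 of 12 runs (adjusted p = 0.0837). The cholesterol synthesis list had a median of 0.22 (0.29 and 0.08 within the sets, adjusted p = 0.00117, or adjusted p = 0.0595 with an estimated correlation). Nrf2 targets and glutathione enzymes had a median of 0.24 (adjusted p = 0.00491, or adjusted p = 0.324 with an estimated correlation). With 1 sample left out its median ran from 0.09 to 0.25, and it was called in 10 of 12 runs. Of these 25 genes 0 passed over all genes, and over the list alone 7 were higher and 1 was lower. Circadian clock output genes, which move with the hour of dissection, had a median of 0.45 (0.27 and 0.76 within the sets, adjusted p = 0.00114, or adjusted p = 0.173 with an estimated correlation). Adipocyte markers were higher beside the metabolic genes, with a median of 0.58 and 0.35 and 1.05 within the sets (adjusted p = 0.00145, or adjusted p = 0.321 with an estimated correlation). Their median ran from 0.18 to 0.77 with 1 sample left out, with the call kept in 11 of 12 runs. Smooth muscle markers had a median of 0.17 with the array set as a term (adjusted p = 0.00248, or adjusted p = 0.143 with an estimated correlation).

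The planned fit called 53 probe sets higher and 165 lower in this comparison, and 2 higher and 2 lower of these were on 430A. Without the 2 outlying arrays, which leaves 1 array in the curcumin group, 2 of the 214 calls on 430B still passed, 170 kept at least 0.5 of their size and 44 did not, and all kept their sign. The remaining array also took part in making these calls, so the kept signs and sizes are in part built in. The log2 difference of Prdm11 was -2.37 ± 0.41 in the planned fit and -2.40 ± 0.50 without the outlying arrays. That of Kcnc1 was 2.02 ± 0.35 and 1.91 ± 0.53, and that of 5430427M07Rik was 2.76 ± 0.62 and 2.98 ± 0.94. That of Acot2 was -1.89 ± 0.39 in the planned fit and -0.54 ± 0.23 without them, and that of Eva1b was -2.40 ± 0.57 and -0.32 ± 0.20. The fit with both changes called 17 higher and 16 lower, and leaving out a sample moved its 430A count of 30 between 0 (without standard-diet TNBS replicate 1 or 3, or curcumin-diet TNBS replicate 1 or 2) and 259 (without curcumin-diet control replicate 3). With arrays centred on their median the planned split was 24 higher and 145 lower.

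**Figure D3:**
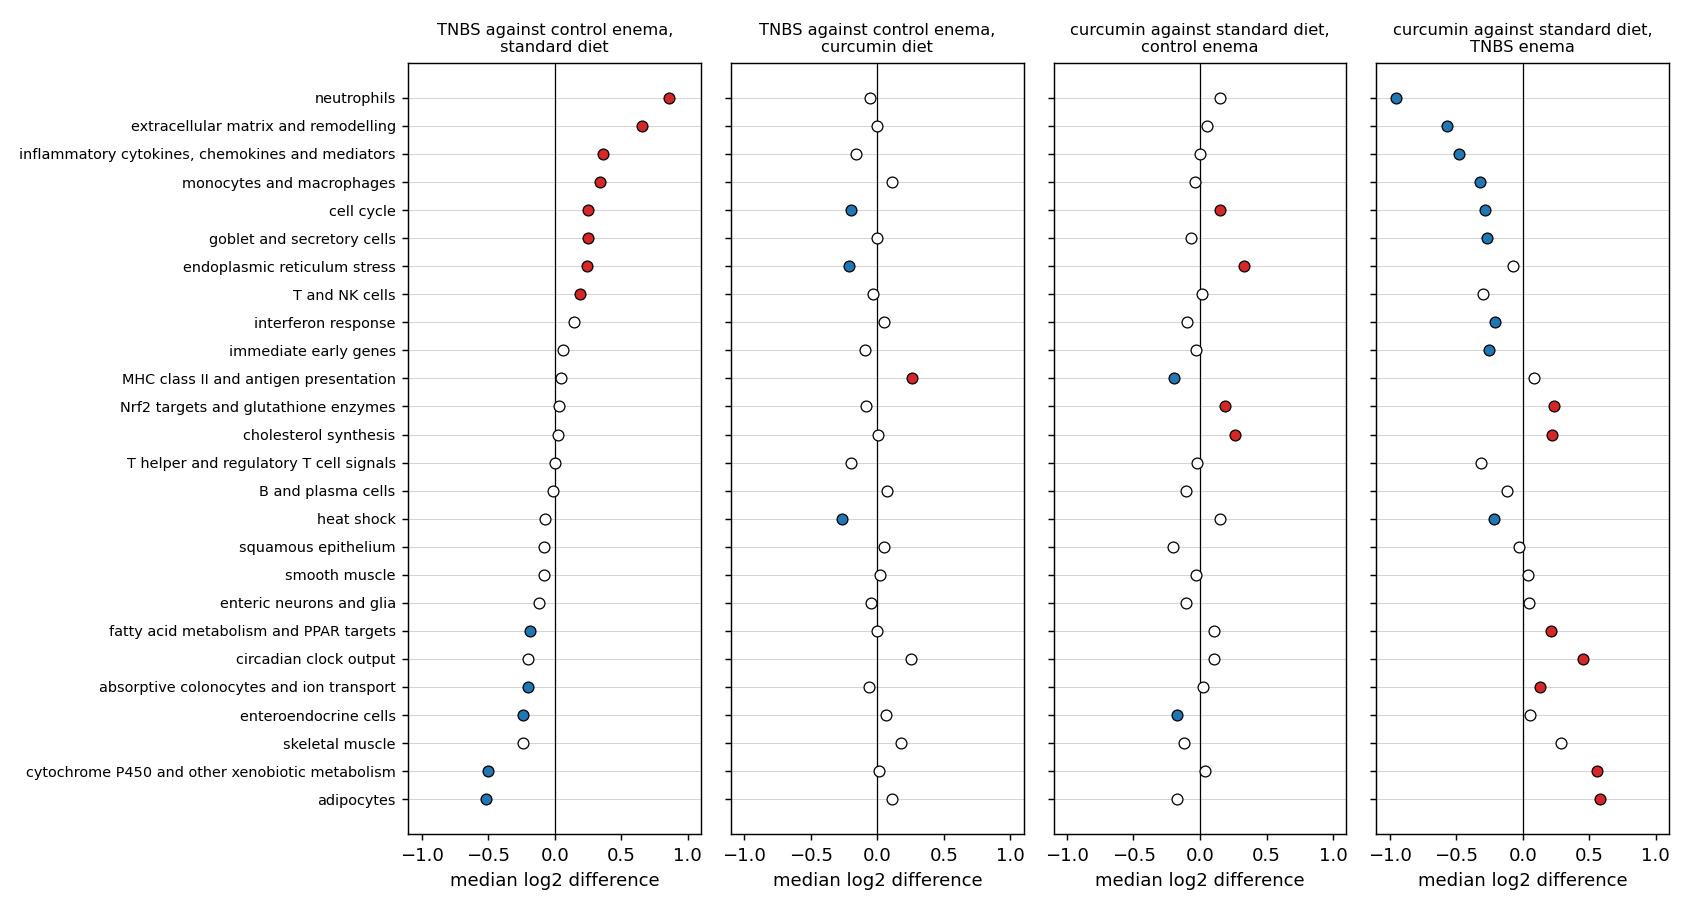
The x axis gives the median log2 difference of each of 26 gene lists (y axis) in the 4 single-factor comparisons, in the planned fit, and filled points mark lists with adjusted p under 0.05, red for higher and blue for lower. The neutrophil list stands at 0.86 for TNBS against control on the standard diet and at -0.95 for curcumin against standard diet under TNBS.

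The interaction asks whether the TNBS effect differed between the diets. The planned fit called 0 probe sets higher and 9 lower, all on 430B (2 and 6 after quantile normalization). Clca4b rose with TNBS on the standard diet and did not pass on curcumin (-1.77 ± 0.53, adjusted p = 0.0941), and its interaction was -6.83 ± 0.76, adjusted p = 0.00276. Rhbdf2, a regulator of cytokine shedding (-3.10 ± 0.37), and Tmem181a (-2.27 ± 0.31) were also called in the planned fit. So were Casp9 (-3.78 ± 0.45), Cpne3 (-2.90 ± 0.47), Fut2 (-2.83 ± 0.46), Srp72 (-1.56 ± 0.25) and 2 probe sets without a named gene. The other probe sets of Casp9 (0.38 and 0.51) and of Cpne3 (0.16 to 0.73) pointed the other way, and those of Fut2 (-1.12) and Srp72 (-0.64) the same way. The 9 calls were made with the curcumin-diet TNBS array that remains without the outlying ones, so kept signs are in part built in. Without the outlying arrays, which leaves 1 array in the curcumin-diet TNBS group, all 9 kept their sign and at least 0.5 of their size. There Clca4b (-7.28 ± 0.93, adjusted p = 0.0439) passed, and Rhbdf2 (-2.91 ± 0.44, adjusted p = 0.0742) and Tmem181a (-1.69 ± 0.28, adjusted p = 0.0951) did not. On 430A 0 probe sets passed in limma, with 1347 at unadjusted p under 0.05. The Lcn2 interaction was -6.03 ± 0.84, adjusted p = 0.122 there, and -5.96 ± 0.88, adjusted p = 0.0949 with the array set as a term.

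At the level of lists, 13 were called in the interaction. It contains the standard-diet TNBS effect with its sign turned, so the 2 tend to opposite signs by construction, and the values are given without a reading of their opposition. The interaction was negative for inflammatory (median -0.54 without and -0.39 with the array set; adjusted p = 2.51e-08; adjusted p = 0.04995 with an estimated correlation), neutrophil (median -1.16 without and -1.25 with the array set; adjusted p = 1.31e-07; adjusted p = 0.173 with an estimated correlation) and macrophage genes (median -0.35 without and -0.44 with the array set; adjusted p = 0.00400; adjusted p = 0.236 with an estimated correlation) and for matrix genes (median -0.66 without and -0.59 with the array set; adjusted p = 6.96e-09; adjusted p = 0.252 with an estimated correlation). It was positive for xenobiotic metabolism (median 0.54 without and 0.55 with the array set; adjusted p = 1.40e-08; adjusted p = 0.173 with an estimated correlation) and, beside it, for adipocyte markers (median 0.63 without and 0.83 with the array set; adjusted p = 0.00400; adjusted p = 0.383 with an estimated correlation). The endoplasmic reticulum stress list was negative (median -0.47 without and -0.44 with the array set; adjusted p = 1.40e-08; adjusted p = 0.173 with an estimated correlation), as this list was higher with TNBS on the standard diet and lower with TNBS on curcumin. With an estimated correlation and the array set as a term 0 lists passed.

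Averaged over the diets, TNBS moved 1 probe set higher and 3 lower in the planned fit, all on 430B. A probe set of the neutrophil chemokine Cxcl1 was higher (1.00 ± 0.16, adjusted p = 0.0479), while the other Cxcl1 probe set had 0.29. Without the 2 outlying arrays 0 of these 4 passed, and all kept their sign and at least 0.5 of their size. The kept signs are in part built in here too, since the remaining array took part in the calls. The stress kinase gene Mapk14 was lower on 1 probe set in the planned fit (-1.19 ± 0.18, adjusted p = 0.0479), while its 3 others had 0.01 to 0.07. On 430A 0 probe sets passed in limma, with 398 at unadjusted p under 0.05. Of the 27 lists 14 were called, and 1 was with an estimated correlation, the macrophage markers (median 0.21 without and 0.21 with the array set; adjusted p = 4.76e-12; adjusted p = 0.0262 with an estimated correlation). Averaged over the enemas, curcumin moved 1 probe set, which maps to several genes. On 430B 0 passed in limma, with 1513 at unadjusted p under 0.05. A list called in this average need not be called under each enema. With the preset correlation, the inflammatory, interferon, xenobiotic and macrophage lists were called for curcumin under TNBS but not under the control enema. Cholesterol synthesis was called under both. Of the lists 19 were called in the average and 5 of these with an estimated correlation. They were cholesterol synthesis (median 0.25 without and 0.25 with the array set; adjusted p = 7.53e-10; adjusted p = 0.00360 with an estimated correlation), inflammatory genes (median -0.20 without and -0.20 with the array set; adjusted p = 1.90e-08; adjusted p = 0.0248 with an estimated correlation), interferon response (median -0.13 without and -0.13 with the array set; adjusted p = 1.29e-05; adjusted p = 0.0324 with an estimated correlation), xenobiotic metabolism (median 0.26 without and 0.26 with the array set; adjusted p = 1.19e-15; adjusted p = 0.0354 with an estimated correlation) and macrophage markers (median -0.17 without and -0.17 with the array set; adjusted p = 2.82e-06; adjusted p = 0.0492 with an estimated correlation).

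Across the 8348 genes of 430A, the TNBS effects on the 2 diets had a correlation of -0.231 (-0.213 with the array set as a term). It ran from -0.417 to 0.0382 with 1 sample left out, the highest without curcumin-diet control replicate 3, so its sign rests on that sample. Here 1 probe set stands for each gene and p is adjusted over the 8348 genes, so the calls differ from those per array type. On the standard diet 6 were called higher without the array set, and 21 higher and 17 lower with it as a term. On curcumin 0 of 8348 were called in either fit. The median ratio of the curcumin-diet to the standard-diet effect over the standard-diet calls was -0.180, and -0.167 with the array set as a term. Between the diet effect under TNBS and the TNBS effect on the standard diet there was a correlation of -0.847 and a covariance of -0.0935. Both comparisons use the same 3 standard-diet TNBS arrays, which alone produce opposition. In 200 simulations without any effect the mean correlation was -0.499 (lowest -0.556) and the mean covariance -0.0317 (lowest -0.0400). The noise of each gene was drawn independently there. Noise shared between genes would widen these ranges, so the lowest values set no bound for the real arrays. Of the 21 genes higher with TNBS and the 15 lower with curcumin in the fit with the array set, 9 were the same, against 0.0377 for independent lists and a mean of 0 in the simulations without any effect. Of the 17 lower and the 23 higher, 12 were the same, against 0.0468 and 0.005 (highest 1). The first value leaves out the shared arrays and the second the effects. With 3 shared arrays no split leaves 2 on each side, so part of these overlaps may come from them.

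Genes of the pancreas, a neighbouring organ, varied widely between samples of the same group in 3 of the 4 groups. The carboxypeptidase gene Cpa1 had signals of 6.30, 12597 and 9486 in the standard-diet control group and 8893, 2759 and 12428 in the standard-diet TNBS group. In the curcumin-diet groups they were 21.7, 5.00 and 5579.5 with control enema and 10027, 19.3 and 1762 with TNBS. The trypsinogen gene Prss2 followed the same pattern, from 165 to 16509 in the standard-diet control group. Neither gene passed in the 4 single-factor comparisons. The medians of the inflammation lists, 0.41 for TNBS against control on the standard diet, were 0.42 with the pancreas score as a covariate. The other lists were not refitted with this score. On 430A the second component carried 26.3% of the variance. It was -29.1, -22.7, -32.6 and -21.9 for the 4 samples with the lowest pancreas score and -1.30 or more for the others. The standard-diet TNBS group has none of these 4 samples, so each comparison with it is partly aligned with the pancreas score.

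**Figure D4:**
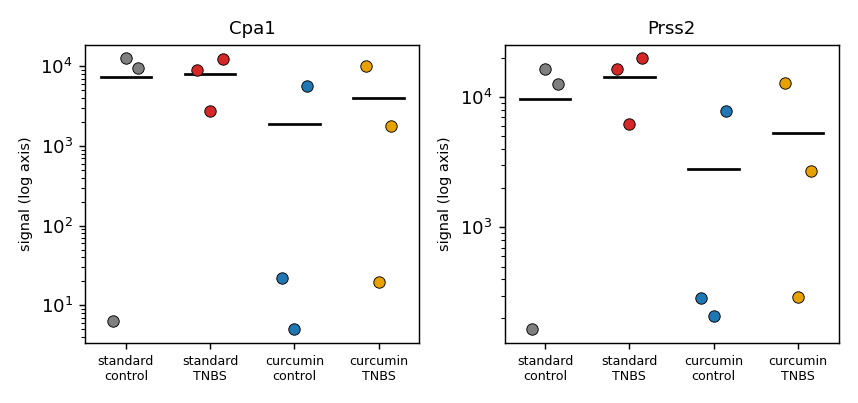
Each point is the signal (intensity, log axis) of Cpa1 or Prss2 on a 430A array, the x axis gives the 4 groups and each bar marks the mean of 3 arrays. In 3 of the 4 groups the samples lie far apart, as for Cpa1 in the standard-diet control group with 6.30 and 12597.

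Some genes were fixed for report whatever their values. Tnf (log2 difference 0.08 ± 0.24, adjusted p = 0.916) and Il17a (0.26 ± 0.19, adjusted p = 0.572) did not differ with TNBS on the standard diet. The prostaglandin synthase gene Ptgs2 differed by 1.04 ± 0.25, adjusted p = 0.0848 and, for curcumin under TNBS, by -1.05 ± 0.25, adjusted p = 0.0800, and did not pass. The quinone reductase gene Nqo1 had -0.11 ± 0.17, adjusted p = 0.803 with TNBS on the standard diet and 0.21 ± 0.17, adjusted p = 0.577 for curcumin under TNBS. The glutathione transferase gene Gstm1 had -0.61 ± 0.14, adjusted p = 0.0759 and 0.70 ± 0.14, adjusted p = 0.0590 in these comparisons. Il6, Ifng, Il10, Il11, Foxp3, Nos2, Hmox1 and Cyp1a1 lay below the signal filter. Values without the filter come from a limma fit that also leaves out the array set. Without the filter, the Il6 signal was 58.3 ± 5.85 in the standard-diet control group and 134 ± 6.94 with TNBS (SD, n = 3), a log2 difference of 1.02 with adjusted p = 0.414. In the same comparison it was 1.25 ± 0.68 for Hmox1, 1.06 ± 0.40 for Il11, 0.41 ± 0.42 for Nos2, 0.26 ± 0.26 for Foxp3, 0.12 ± 0.47 for Cyp1a1, 0.00 ± 0.29 for Il10 and -0.05 ± 0.35 for Ifng, with adjusted p = 0.513 or more. For curcumin under TNBS it was -1.13 for Il6, -0.63 for Hmox1, -0.55 for Il11, -0.76 for Nos2, -0.10 for Foxp3, 0.90 for Cyp1a1, -0.02 for Il10 and 0.16 for Ifng, with adjusted p = 0.306 or more. The lists of T helper and regulatory T cell signals, B and plasma cells, enteric neurons and glia, skeletal muscle and squamous epithelium were called in none of the 4 single-factor comparisons of the planned fit. On the standard diet their medians with TNBS were 0.00, -0.01, -0.12, -0.24 and -0.08. Under TNBS, with the array set as a term, the T helper and regulatory T cell list stood lower on curcumin (-0.43, adjusted p = 0.0491, or adjusted p = 0.242 with an estimated correlation), as did T and NK cell markers (-0.45, adjusted p = 0.00358, or adjusted p = 0.229 with an estimated correlation). No red blood cell marker was above the filter.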

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

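Of the tests in this part, those on the difference between the array sets, on the array-level shift of the 2 430B arrays, on repeat arrays of 1 RNA, with the adipocyte score or with both terms, and the counts with the array set as a term were chosen only after the result was seen, while those with the pancreas score alone, on the 430A arrays of the 2 samples and on the 430B pancreas list were chosen before their own result but after the data had been examined. The results given here were picked because the TNBS effect differed between the diets by a test of the interaction. The planned fit gave 9 probe sets. The log2 interaction was -6.83 for Clca4b, -3.10 for Rhbdf2 and -2.27 for Tmem181a. The median log2 interaction of the lists was -0.54 for inflammatory genes, -1.16 for neutrophil markers, -0.35 for macrophage markers, -0.66 for matrix genes, -0.25 for goblet and secretory markers, -0.43 for cell cycle genes, -0.47 for endoplasmic reticulum stress genes and -0.36 for heat shock genes. It was 0.23 for MHC class II genes, 0.23 for enteroendocrine markers, 0.54 for xenobiotic metabolism, 0.63 for adipocytes and 0.37 for circadian clock output. With an estimated correlation 1 of these 13 lists was called, the inflammatory genes at adjusted p = 0.04995, and 0 were when the array set was a term as well (lowest adjusted p = 0.118). With the array set as a term and the planned correlation, goblet markers (adjusted p = 0.570), heat shock (0.160) and MHC class II (0.139) lost their call. In the planned fit with an estimated correlation, the adjusted p was 0.173 for neutrophils, endoplasmic reticulum stress and xenobiotic metabolism, 0.236 for macrophages, 0.252 for matrix genes and 0.383 for adipocytes. It was 0.383 for goblet, cell cycle, heat shock, MHC class II and clock genes and 0.182 for enteroendocrine markers. With 1 sample left out, MHC class II was called in 7 of 12 runs, enteroendocrine markers and circadian clock output in 9 each, goblet markers in 10, and macrophages, adipocytes and heat shock in 11.

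The inflammation lists stood higher with TNBS on the standard diet, with a median log2 difference of 0.41 over their 45 members. If a difference between the 2 array sets were the cause, the value would shrink with the array set as a term of the fit, but it was 0.51, or 1.25 times as large, with 0.42 and 0.64 within the sets. Pancreas tissue is argued against as well: with the pancreas score as a covariate the median was 0.42, or 1.04 times as large, and with both terms 0.49. With an adipocyte score it was 0.38. The colitis itself, which the design names, stays open, as does a difference between the pools of the groups, which no value here tests.

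The 2 430B arrays of curcumin-diet TNBS replicates 2 and 3 lie apart from the other 10. A difference of the samples themselves is argued against by their 430A arrays, where the drop in correlation was -0.00915 against 0.134 on 430B, a ratio of -0.0684. The shift of the 2 430B arrays had a correlation of 0.623 with the shift that parts the 430A array sets, over 100 probe sets present on both array types. With the groups in the model, the 430B shift sets replicates 2 and 3 against replicate 1 of this group. Replicate 1 lies in array set 1 and the other 2 in array set 2, so the 430A shift holds the same contrast in part. A difference between these samples would enter both shifts. The correlation therefore cannot tell it from a step at the level of the array. Between 2 probe sets of a gene, the shift had a correlation of 0.0869 on 430A (1911 genes) and 0.0890 on 430B (1329 genes). The TNBS difference on 430A had 0.433. On 430A the shift thus followed probe sets more than genes, as a step at the level of the array would give. For 430B no such reference was computed.

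Pancreas markers differed between samples of a group. Repeat arrays of 1 RNA are argued against, since the range of the pancreas score within a group was up to 17.3 times that of the median gene (17.3, 4.14, 11.7 and 17.3 in the 4 groups). Pancreas tissue carried into some samples could produce this, but the test left it open: of the 4 samples with the lowest score on 430A, 3 were among the 4 lowest on 430B, which random draws reach or pass in 6.67% of cases. The sample that did not match was curcumin-diet TNBS replicate 2 (6.91 on 430A, 8.46 on 430B), whose 430B array is 1 of the 2 outlying ones. Apart from the 2 outlying arrays, the 3 samples lowest on 430A were also the 3 lowest on 430B. Their 430B scores were 7.42, 7.72 and 8.12, and the next was 8.17. This was seen after the result. Only 2 pancreas genes were measured on 430B. No biological explanation was tested.

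With 3 samples against 3 there are 10 splits, so no share below 0.05 can be reached. For TNBS against control on the standard diet, the real groups gave 2 probe sets and the highest other split 0, the same holds for 63 and 0 on 430A with the array set as a term, and lists were 13 and 13. For TNBS on curcumin the values were 55 and 108 probe sets and 5 and 11 lists. For curcumin under the control enema they were 1 and 1, and 7 and 12. For curcumin under TNBS they were 218 and 2, 30 and 0 with the array set as a term, and 17 and 16 lists. Counting the real groups, as many or more came from 1 of 10 splits for the probe sets of TNBS on the standard diet in both fits and from 2 for its lists. They came from 2 and 8 of 10 for probe sets and lists of TNBS on curcumin, from 3 and 7 for curcumin under the control enema and from 1 of 10 for all values of curcumin under TNBS.

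For the interaction, 2 of 100 splits gave as many as 9 probe sets, and the highest other value, 3558, came from the split that follows the 2 array sets. For its lists 13 of 100 gave 13 or more (highest other 16), so some other splits gave as many lists. These splits exchange the enemas within each diet. They take away the TNBS effect along with its difference between the diets, so they cannot judge the interaction alone. For TNBS averaged over diets, 3 of 100 gave 4 or more probe sets. The highest other value, 188, came from a split that puts both outlying 430B arrays in 1 group, as the real groups also do. For lists, 5 of 100 gave 14 or more (highest other 16). For curcumin averaged over enemas, 16 of 100 gave 1 or more probe sets (highest other 451) and 1 of 100 gave 19 lists (highest other 18).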

How the results depend on the processing

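The tests with the array set, without the 2 outlying 430B arrays and with the pancreas score were chosen only after the result was seen. No paired analysis was possible because the replicate numbers follow the order of the samples and pair nothing between groups. Of the values under other settings for the named genes, 2084 kept their sign and their side of the threshold, 379 lost their call and 196 gained one. Another 58, such as values of Tnf, Il17a and Muc2, changed sign or went to 0 with no call in either setting, and 0 called values changed sign. Clca4b passed in 23 of 23 settings with TNBS on the standard diet, Lcn2 in 19 of 23, Saa3 in 11 of 24 and Il1b in 6 of 24. Counts follow in the order TNBS on the standard diet (2), TNBS on curcumin (55), curcumin under control enema (1), curcumin under TNBS (218), interaction (9), TNBS averaged (4) and curcumin averaged (1), and only those that differ from the planned count by more than 1.5 times are given.

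A pseudocount of 1 gave 27 for TNBS on curcumin, and one of 64 gave 11 for TNBS on the standard diet and 0 for TNBS averaged. Without the filter the counts were 11, 25, 100, 4, 0 and 0, in order but without curcumin under control enema. A filter at the 60th percentile gave 8 for TNBS on curcumin, 0 for curcumin under control enema, 0 for TNBS averaged and 4 for curcumin averaged. Quantile normalization gave 14 for TNBS on the standard diet, 2 for TNBS averaged and 4 for curcumin averaged, and centring on the median gave 5 for the interaction. Without a trend the counts were 12 for TNBS on curcumin, 41 for curcumin under TNBS, 5 for the interaction and 0 for curcumin averaged. Array weights gave 224, 2971, 2, 4766, 2529, 619 and 622. An adjusted p under 0.01 left 3, 0, 13, 4, 0 and 0 from TNBS on curcumin on. A change of at least 1.5-fold altered 0 counts. With only the 6 arrays compared the counts were 42, 1, 0 and 42.

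The array set as a term gave 64 for TNBS on the standard diet. Without the 2 outlying arrays, which leaves 1 array of the curcumin-diet TNBS group on 430B, the counts were 2, 0, 7, 1, 0 and 2 from TNBS on curcumin on. Both together gave 64, 2, 0, 33, 1, 0 and 2. The array set with the pancreas score gave 33 for TNBS on the standard diet, 3 for curcumin under control enema and 0 for curcumin averaged. Leaving out 1 sample at a time, the counts ran from 1 to 71, 3 to 2743, 0 to 4, 5 to 2620, 3 to 1399, 0 to 740 and 0 to 669. The highest came without curcumin-diet control replicate 3 in the first and without curcumin-diet TNBS replicate 1 in those above 100. On 430A with the array set, the count for TNBS on the standard diet (63) ran from 0 to 292 and that for curcumin under TNBS (30) from 0 to 259.

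Gene lists called were 13, 5, 7, 17, 13, 14 and 19 in the same order. An estimated correlation left 2, 0, 2, 1, 1, 1 and 5. The array set gave 8 for TNBS on curcumin. Leaving out 1 sample, curcumin under control enema ran from 6 to 13 lists, and the others ran from 9 to 16, 4 to 7, 13 to 19, 9 to 16, 11 to 18 and 15 to 19. The correlation of the TNBS effects was -0.231, and -0.417 to 0.0382 with 1 sample left out. The covariance of diet and TNBS effects less the simulated value was -0.0618, and -0.0761 to -0.0412 with 1 sample left out. A stricter threshold can only lower a count by construction. Fewer samples gave both higher and lower counts. For changes other than those from a stricter threshold the cause was not tested. Genes with a mean signal below about 179.5 on 430A or 195.4 on 430B were not tested, which limits what can be said of low cytokine genes.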

Other observations

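The counts with the array set as a term and the fold changes from that fit were chosen only after the result was seen, while the list test was chosen before. Acute-phase and antimicrobial genes differed within the curcumin-diet control group. Replicate 3 of that group, chosen after its values were seen, had Reg3g at 2458, against 874 and 1173 in replicates 1 and 2, and Lcn2 at 710.1, against 82.1 and 101. These signals lie below those of the standard-diet TNBS group. Without this sample the count for TNBS on the standard diet with the array set as a term was 292 instead of 63, and that for curcumin under TNBS was 259 instead of 30. Its 3 pooled mice, if it is a separate pool, were not examined further here.

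Clock output genes stood higher on curcumin under TNBS, with a median log2 difference of 0.45 (adjusted p = 0.00114). The call was lost at adjusted p = 0.173 with an estimated correlation. The repressor gene Nr1d2 had a log2 difference of 0.96 ± 0.23, adjusted p = 0.0883 and the transcription factor gene Dbp of 1.36 ± 0.36, adjusted p = 0.104, both in the fit with the array set, and neither passed over all genes. Both were chosen after their values were seen. The labels give no hour of dissection, so an hour that differed between groups was not tested.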
